A study of Mus musculus with 8 samples.

How the data were processed

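Gene expression was measured in 8 samples of CD11b+ cells of mouse brain, 4 after saline and 4 after LPS, on 1-colour Agilent arrays. Per the labels, 50 ng of total RNA per sample was labelled with Cy3. Per the submitters' processing notes and the file headers, the spots were quantified with Agilent Feature Extraction 12.0.3.1. The deposited scanner files hold intensity values, and per the file headers the processed signal had its background subtracted by spatial detrending, with surrogate values for spots not above background and no scaling between arrays. The authors' deposited value table holds log2 values, which by comparison with the scanner values (correlations near 1.00 on every array) are shifted by each array's 75th percentile and centred on each probe's median over the 8 arrays. Its column medians were -0.07 to 0.08, its direction was that of the scanner values, and how the authors chose this processing is not given in the sources used here.

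Control spots and spots marked as outliers were left out, spots of one probe were averaged, and 6 probes with no usable spot on some array were left out. No spot was saturated. Of 56605 probes, 35405 were named through their RefSeq accession in a table of assembly GRCm38.p6, 9124 by symbol and 25 by synonym, while 12051 kept the name in the file. The main values were log2 processed signal minus each array's 75th percentile. Probes well above background on at least 4 of 8 arrays were kept (35494), and each gene was represented by its probe with the highest mean signal, which left 22509 genes. Among 4404 changed genes with more than 1 probe, all probes went the same way in 3496, and in 293 a probe was called in the opposite direction. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene not well above background on any array of a group has only a bound. It sets the mean of the bright group against the higher of each dim array's lowest signal well above background and the probe's own signal. The bounds were computed from the main values only and carry no standard error, so another scaling would move them.

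Fixed before the data were examined were 36 gene lists, of which sex markers served only as a check of labels. The other 35 were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. At the preset correlation camera also called 3 to 13 lists in splits of the arrays that balanced the treatment, which limits every camera call below. The named genes followed a rule fixed at the same time. It took the 10 largest increases and 10 largest decreases among changed genes with a symbol whose groups do not overlap and that are well above background on at least 3 of 4 arrays per group. It also took up to 4 genes per direction seen in only 1 group, ranked by their bound, up to 3 risen and 3 fallen members of each list (or the 2 with the highest signal where none passed), and 12 genes named in advance. List members beyond 2 per direction may be left out, and 1 further list member is not reported here.

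On simulated data with the means and spreads of these 22509 genes, and 200 genes changed between saline and LPS, limma recovered 11 of 50 genes at a log2 change of 0.5, 36 of 50 at 1, 45 of 50 at 2 and 50 of 50 at 4, with 11 unchanged genes called. The simulation drew each gene independently and changed far fewer genes than were called in the data, so these rates do not give the sensitivity there. The alternatives covered scaling, background correction, the filter on dim probes, the choice of probe, the variance model, array weights, slide row and column as blocks, the authors' values and leaving out each array in turn. Normexp background correction added an offset of 50 to every signal, against a median processed signal of 11.7 to 21.5 on the arrays. The offset alone shrinks the log2 changes of dim genes, and normexp without it was not run. The labels give no replicate numbers, so none pair the samples, and the numbers used here only name them in order. Each slide column held 1 saline and 1 LPS array of the same such number, so the fit with slide column as a block (13620 genes changed) is also the fit by that number. No 2 arrays of a group held the same values. Tubes were separate pools of 2 mice each. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.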

Results

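CD11b+ cells, the fraction of brain cells that carries the integrin found on microglia and other myeloid cells, were sorted with magnetic beads from 7 day old male C57BL/6N mice 24 h after saline or lipopolysaccharide (LPS, a component of the outer membrane of Gram-negative bacteria). Each of the 8 tubes held the brains of 2 mice, with 4 tubes per treatment, and RNA from each tube was hybridised to 1 array. On the saline arrays 61.9% to 66.0% of probes were well above background, and on the LPS arrays 58.6% to 63.2%. The median processed signal was 15.5 to 21.5 on the saline arrays and 11.7 to 17.3 on the LPS arrays. The number of arrays limits the precision of every value. All changes below are log2 LPS minus saline ± standard error with n = 4 arrays per group, and p-values are adjusted.

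The comparison asked how sorted brain cells of postnatal mice differed 24 h after LPS. Saa3, a serum amyloid A protein made in inflammation (12.27 ± 0.23), and the chemokine Ccl5 (6.31 ± 0.17) were among the largest increases. All 35 measured genes of the type I interferon list and all 40 of the cell cycle list rose. P2ry12, the purinergic receptor typical of resting microglia, fell by 1.55 ± 0.20, and the MHC class II gene H2-Ab1 fell by 1.38 ± 0.21. Markers of astrocytes fell in 13 of 14 measured genes. In all, 11104 of 22509 genes tested with limma changed, 6267 higher and 4837 lower, and 2099 of them changed at least 2-fold, 805 higher and 1294 lower (or 1536 higher and 732 lower when scaled to each array's median, and 422 and 225 with normexp background). Of the genes that changed, 56.4% were higher, but scaling to each array's median gave 72.8% and scaling over probes well above background on all arrays gave 40.1%, with the median of all genes moving from 0.02 to 0.24 and -0.13. The groups did not overlap in 44.7% of all genes tested, against 2.86% by chance. Without LPS replicate 3, 13262 genes changed and 3415 changed at least 2-fold, with 2311 lower. Normexp background added an offset of 50, which by itself shrinks the changes of dim genes wherever its values are given. With normexp background and the 75th percentile 647 genes changed at least 2-fold, and the fold of 49 of 177 named genes past the test was smaller by over 1.5 times. The median signal of each array as a covariate ended the calls of 33 of them, and scaling to each array's median ended 18 and turned 1.

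**Figure D1:**
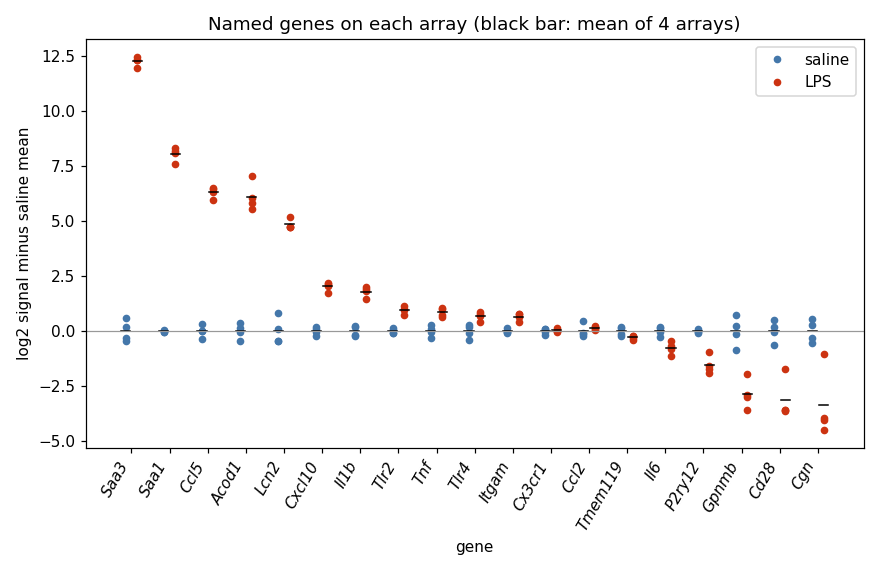
Each gene's normalised log2 signal on each of the 8 arrays, minus the saline mean of that gene, with saline arrays in blue, LPS arrays in red and bars for the mean of 4 arrays. Saa3 stood 12.27 above the saline mean on average and P2ry12 stood at -1.55.

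Among the largest increases were further secreted or antimicrobial proteins. Saa1, another serum amyloid A, rose by 8.05 ± 0.14, Lcn2, which withholds iron from bacteria, by 4.86 ± 0.28, and Cfb, a component of the alternative complement pathway, by 4.27 ± 0.21. Acod1, the enzyme that makes itaconate, rose by 6.11 ± 0.33. The increases also took in the B cell and myeloid surface protein Cd72 (4.47 ± 0.23), the scavenger receptor Marco (4.37 ± 0.66, with a saline SD of 1.46), the nucleic acid sensor Zbp1 (4.07 ± 0.23) and the serpin Serpina3g (3.98 ± 0.24). Genes not well above background on any saline array gave lower bounds: Cxcl13, a B cell chemoattractant, was at least 92.8-fold higher, Saa2 at least 41.1-fold, Slfn4 at least 14.5-fold and Oas3 at least 12.8-fold higher, where the dim value was each array's lowest signal well above background or the probe's own signal, whichever was higher. With normexp background and the 75th percentile the changes were 2.95 for Cxcl13, 1.97 for Saa2, 1.07 for Slfn4 and 0.94 for Oas3, and those of Saa3 10.63, Saa1 7.21, Acod1 5.07, Zbp1 3.39 and Serpina3g 2.19. In the values minus the 75th percentile, the largest decreases by the rule were in the tight junction protein Cgn (-3.38 ± 0.71), Asb11 (-3.38 ± 0.54), Mamdc2 (-3.32 ± 0.52), the Wnt antagonist Dkk2 (-3.26 ± 0.49), the T cell costimulatory receptor Cd28 (-3.13 ± 0.45), the transmembrane glycoprotein Gpnmb (-2.86 ± 0.41), the metalloprotease Adamts16 (-2.72 ± 0.39), the proton pump subunit Atp6v0d2 (-2.69 ± 0.50), the cytokine Tslp (-2.65 ± 0.45) and elastin, Eln (-2.63 ± 0.43). The change of Cgn was -2.37 and not past the test with the median signal of each array as a covariate, and -4.16 without LPS replicate 3. With normexp background and the 75th percentile Gpnmb was -2.71, and the others had smaller folds by over 1.5 times: Cgn -1.93, Asb11 -1.27, Mamdc2 -1.24, Dkk2 -1.14, Cd28 -2.03, Adamts16 -1.10, Atp6v0d2 -1.86, Tslp -0.90 and Eln -1.42. Of genes not well above background on any LPS array, Mmp12 was at least 3.48-fold lower, Krt15 at least 3.43-fold, Acta1 at least 2.98-fold and Vstm2a at least 2.69-fold lower. Mmp12 was -0.21, Krt15 -0.20, Acta1 -0.15 and Vstm2a -0.13 (not past the test) with normexp background and the 75th percentile. Mamdc2 was -2.62, Adamts16 -1.94, Tslp -1.93 and Eln -1.60 with the median signal of each array as a covariate.

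Interferon-response genes rose together. In the type I interferon list 35 of 35 measured genes rose and 0 fell (35 and 0 adjusted over the list alone), with a median of 2.07 (camera adjusted p = 7.75e-20, and adjusted p = 0.518 with an estimated correlation). Examples were the sensor Zbp1, and Oasl1 of the oligoadenylate synthetase family (3.69 ± 0.21). In the list of interferon gamma targets and guanylate binding proteins 16 of 20 measured genes rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 1.30 (camera adjusted p = 4.92e-07, and adjusted p = 0.518 with an estimated correlation). The chemokine Cxcl9 (4.96 ± 0.56, well above background on 2 of 4 saline arrays, 4.57 with signals floored at the lowest well above background and 1.86 with normexp background) and the GTPase Gbp2 (3.34 ± 0.23) rose, and Ciita, the activator of MHC class II genes, fell by 0.97 ± 0.13. The mean change of the type I list was 1.84 on LPS replicate 3 and 2.15 to 2.42 on the other LPS arrays, and without LPS replicate 3 the counts were 35 higher and 0 lower, with 17 higher and 1 lower for interferon gamma targets. Cxcl9 was 4.07 with the median signal of each array as a covariate.

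Cytokine genes moved in both directions. Among cytokines 14 of 23 measured genes rose and 5 fell (15 and 5 adjusted over the list alone), with a median of 0.69 (camera adjusted p = 0.00426, and adjusted p = 0.518 with an estimated correlation). Il1b, the product of which is cleaved in the inflammasome, rose by 1.80 ± 0.16 and Tnf by 0.85 ± 0.14, while Il6 fell by 0.77 ± 0.16. Ifng (2.79 ± 0.13) rose, Csf3, the granulocyte growth factor, was at least 3.23-fold higher, Csf1, the macrophage growth factor, fell by 1.83 ± 0.24, and Lif, well above background on 2 of 4 LPS arrays, fell by 1.01 ± 0.33 (-0.65 with signals floored at the lowest well above background and -0.007 and not past the test with normexp background). Among chemokines 7 of 23 measured genes rose and 5 fell (7 and 5 adjusted over the list alone), with a median of 0.01 and a mean of 0.93 (camera adjusted p = 0.409). Cxcl10 rose by 2.03 ± 0.13, whereas the change of Ccl2, which draws monocytes, was 0.14 ± 0.15 (adjusted p = 0.438), or 0.29 and past the test without saline replicate 2 and -0.15 with quantile normalization. The median of the chemokine list was -0.17 with quantile normalization. Ccl24 (-1.39 ± 0.22) and Ppbp (-1.32 ± 0.24) fell. The call of Lif ended in leave-one-out fits: Lif (without saline 1, saline 2, LPS 2, saline 3, LPS 4, -1.05 to -0.78). Ifng was 0.72, Csf3 0.42 and Ppbp -0.51 with normexp background and the 75th percentile. Lif was -0.92 (not past the test) with the median signal of each array as a covariate. Lif was -0.80 (not past the test) when scaled to each array's median. Lif was -0.75 (not past the test) with quantile normalization.

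In the list of Toll-like receptor and NF-kB signalling 16 of 37 measured genes rose and 5 fell (16 and 5 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.0261, and adjusted p = 0.659 with an estimated correlation). Tlr2 rose by 0.96 ± 0.11, Cd14, the LPS co-receptor, by 0.75 ± 0.15 (0.40 with quantile normalization), and Tlr4, the LPS receptor, by 0.68 ± 0.17. The kinase gene Ikbke (3.29 ± 0.20, or 2.47 as the mean of its probes) and the inhibitory Irak3 (2.11 ± 0.18) rose, and Cd180 (-0.65 ± 0.09) and Ly96, the partner of Tlr4 (-0.39 ± 0.11), fell. In the inflammasome list 11 of 16 measured genes rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 0.00598, and adjusted p = 0.566 with an estimated correlation). Mefv, the gene of pyrin, rose by 2.58 ± 0.20, and the sensor gene Nlrc4 fell by 0.55 ± 0.12. The mean change of the signalling list was 0.25 on LPS replicate 3 and 0.47 to 0.51 on the other LPS arrays, and that of the inflammasome list was 0.37 on LPS replicate 3 and 0.65 to 0.68 on the other LPS arrays. Without LPS replicate 3 the counts were 18 higher and 4 lower for signalling and 11 higher and 1 lower for the inflammasome. With quantile normalization the camera adjusted p rose to 0.308 for signalling and 0.0503 for the inflammasome. A call ended in leave-one-out fits: Ly96 (without LPS 1, saline 3, saline 4, LPS 4, -0.39 to -0.33). With the median signal as a covariate the median of the signalling list was -0.020 and its call ended (camera adjusted p = 0.149), and Tlr4 was 0.32 and not past the test. Ikbke was 1.505, Irak3 1.51 and Mefv 1.58 with normexp background and the 75th percentile. Ly96 was -0.29 (not past the test) and Nlrc4 -0.45 (not past the test) with the median signal of each array as a covariate. Ly96 was -0.18 (not past the test) and Nlrc4 -0.33 (not past the test) when scaled to each array's median. Ly96 was -0.17 (not past the test) as the mean of a gene's probes.

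Antigen presentation genes formed 2 lists, which no test compared. For MHC class I and the proteasome 17 of 20 measured genes rose and 2 fell (17 and 2 adjusted over the list alone), with a median of 0.76 (camera adjusted p = 1.12e-05, and adjusted p = 0.518 with an estimated correlation). The peptide transporter gene Tap1 (1.46 ± 0.15) and the immunoproteasome subunit gene Psmb9 (1.42 ± 0.18) rose, and H2-Q6 (-0.73 ± 0.11) and H2-Q4 (-0.32 ± 0.09) fell. For MHC class II and costimulation 3 of 15 measured genes rose and 8 fell (4 and 8 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 0.138). H2-Aa (-1.50 ± 0.21) and H2-Ab1 fell, and the inhibitory ligand Cd274 (1.32 ± 0.17) and Cd40 (1.0 ± 0.18) rose. In the complement list 13 of 21 measured genes rose and 3 fell (13 and 3 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.00424, and adjusted p = 0.518 with an estimated correlation). Beside Cfb, the complement regulator Cd55 (2.29 ± 0.18) and the central component C3 (1.94 ± 0.19) rose, and Itgax (-1.77 ± 0.32) and Cd59a (-0.51 ± 0.12) fell. Among phagocytic and Fc receptors 11 of 25 measured genes rose and 9 fell (11 and 9 adjusted over the list alone) (camera adjusted p = 0.608), with the IgG receptor Fcgr4 (2.71 ± 0.18) among the risen, and the beta-glucan receptor Clec7a (-1.30 ± 0.20) and Megf10 (-1.20 ± 0.14) among the fallen. The mean change of the class I list was 0.50 on LPS replicate 3 and 0.81 to 0.88 on the other LPS arrays, and without LPS replicate 3 the counts were 17 higher and 2 lower for class I and 4 higher and 8 lower for class II. Cd40 was 0.40 and Megf10 -0.26 with normexp background and the 75th percentile. H2-Q4 was -0.29 (not past the test) with the median signal of each array as a covariate. H2-Q4 was -0.11 (not past the test) and Cd59a -0.29 (not past the test) when scaled to each array's median.

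Genes of resting microglia fell. In the homeostatic list 0 of 24 measured genes rose and 18 fell (0 and 19 adjusted over the list alone), with a median of -0.42 (camera adjusted p = 3.00e-06, and adjusted p = 0.518 with an estimated correlation). The fructose transporter gene Slc2a5 (-1.87 ± 0.26) fell beside P2ry12. Tmem119 was -0.29 ± 0.11 (adjusted p = 0.0578), or -0.36 and past the test without saline replicate 4. Cx3cr1, the fractalkine receptor, was 0.03 ± 0.09 (adjusted p = 0.792), and turned to -0.15 with quantile normalization and to -0.13 when scaled over probes well above background on all arrays. It was -0.01 without LPS replicate 1 and -0.03 without saline replicate 3. Itgam, the gene of CD11b, rose by 0.66 ± 0.10. In the list of disease-associated microglia 6 of 27 measured genes rose and 12 fell (6 and 12 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 0.0799), or -0.24 and past the test without saline replicate 3 and 0.05 when scaled to each array's median. Gpnmb and Ank (-2.09 ± 0.28) fell, and Cd52 (2.12 ± 0.17) and Cst7 (1.0 ± 0.24) rose. Among border macrophage markers 1 of 17 measured genes rose and 9 fell (1 and 9 adjusted over the list alone) with a median of -0.50 (camera adjusted p = 0.00527, and adjusted p = 0.528 with an estimated correlation). Siglec1, a sialic acid receptor that interferon also induces, rose by 2.10 ± 0.15, and the lectin genes Cd209b (-2.53 ± 0.44) and Clec10a (-1.46 ± 0.16) fell. The mean change of the homeostatic list was -0.42 on LPS replicate 3 and -0.68 to -0.48 on the other LPS arrays, and that of border macrophage markers was -0.25 on LPS replicate 3 and -0.59 to -0.46 on the other LPS arrays. Without LPS replicate 3 the counts were 0 higher and 18 lower and 1 higher and 10 lower. Cd209b was -1.21 with normexp background and the 75th percentile. Cst7 was 0.49 (not past the test) and Cd209b -1.85 with the median signal of each array as a covariate.

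Among lysosomal genes 4 of 28 measured genes rose and 5 fell (4 and 5 adjusted over the list alone) (median -0.06, or 0.15 when scaled to each array's median, camera adjusted p = 0.481). The protease genes Ctsc (1.60 ± 0.14, or 0.94 as the mean of its probes) and Ctsh (0.60 ± 0.10) rose, and Atp6v0d2 and Hexa (-0.60 ± 0.11) fell. In the TGF-beta list 2 of 21 measured genes rose and 10 fell (2 and 10 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.0285, and adjusted p = 0.518 with an estimated correlation). Tgfbi (1.20 ± 0.18) and Smad6 (0.32 ± 0.07) rose, and Ltbp1 (-1.45 ± 0.36, or -0.43 and not past the test as the mean of its probes) and Lrrc32 (-1.28 ± 0.19), whose products hold latent TGF-beta, fell. Among immediate early and heat shock genes 5 of 30 measured genes rose and 16 fell (5 and 17 adjusted over the list alone), with a median of -0.27 (camera adjusted p = 0.00393, and adjusted p = 0.518 with an estimated correlation). Hspa1b (-1.18 ± 0.32) and Egr2 (-1.02 ± 0.20) fell, and Hsp90ab1 (0.64 ± 0.10) and Dusp2 (0.49 ± 0.14) rose. Among glucocorticoid response genes 5 of 17 measured genes rose and 4 fell (5 and 5 adjusted over the list alone) (median -0.16, or 0.05 when scaled to each array's median, mean 0.17, camera adjusted p = 0.588). Beside Lcn2, Hif3a rose (0.84 ± 0.26), and the kinase genes Pdk4 (-0.99 ± 0.25) and Sgk1 (-0.74 ± 0.13) fell. Leave-one-out fits ended the calls of Dusp2 (without LPS 1, LPS 2, saline 3, saline 4, 0.40 to 0.49) and Hif3a (without saline 1, saline 3, saline 4, 0.78 to 0.85). Ltbp1 was -0.23 and Pdk4 -0.28 with normexp background and the 75th percentile. Ltbp1 was -0.68 (not past the test), Hspa1b -0.45 (not past the test), Dusp2 0.23 (not past the test), Hif3a 0.73 (not past the test) and Pdk4 -0.69 (not past the test) with the median signal of each array as a covariate. Hexa was -0.39 (not past the test) when scaled to each array's median. Dusp2 was 0.14 (not past the test) with quantile normalization. Smad6 was 0.16 (not past the test) and Hif3a 0.68 (not past the test) when scaled over probes well above background on all arrays.

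Cell cycle and oxidative phosphorylation genes were higher in LPS. In the cell cycle list 40 of 40 measured genes rose and 0 fell (40 and 0 adjusted over the list alone), with a median of 0.98 (camera adjusted p = 5.32e-14, and adjusted p = 0.518 with an estimated correlation). Cyclin E1, Ccne1, rose by 1.37 ± 0.17, and the mitotic checkpoint kinase gene Bub1 by 1.21 ± 0.14. For oxidative phosphorylation 30 of 32 measured genes rose and 0 fell (30 and 0 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 1.15e-08, and adjusted p = 0.518 with an estimated correlation), including Cycs, the gene of cytochrome c (1.21 ± 0.13), and Uqcrq (0.93 ± 0.14). Cox7b of this list was 0.91, or 0.56 with quantile normalization. Over all genes in the highest 10% by signal the median change was 0.34. The mean change of the cell cycle list was 0.64 on LPS replicate 3 and 0.88 to 1.18 on the other LPS arrays, and that of oxidative phosphorylation was 0.35 on LPS replicate 3 and 0.66 to 0.78 on the other LPS arrays. Without LPS replicate 3 the counts were 40 higher and 0 lower and 30 higher and 0 lower. For glycolysis 10 of 23 measured genes rose and 3 fell (10 and 3 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.0471, and adjusted p = 0.659 with an estimated correlation). Gapdh (0.96 ± 0.14) and Pkm (0.81 ± 0.13) rose, and the phosphofructokinase genes Pfkl (-0.37 ± 0.11) and Pfkm (-0.30 ± 0.08) fell. With quantile normalization the median of the glycolysis list was -0.001 and its call ended. Without LPS 1, LPS 4 or saline 3 its median was 0.24 to 0.26 and not past the test. Among cholesterol synthesis genes 5 of 23 measured genes rose and 2 fell (4 and 0 adjusted over the list alone) (camera adjusted p = 0.163), with Pmvk (0.67 ± 0.12) and Fdps (0.60 ± 0.10) risen, and Hmgcs1 (-0.20 ± 0.07) fallen. Scaled to each array's median, Hmgcs1 was 0.012 and not past the test. Leave-one-out fits ended the calls of Pfkl (without LPS 1, LPS 2, saline 3, saline 4, -0.36 to -0.30), Pfkm (without LPS 1, LPS 2, -0.28 to -0.26) and Hmgcs1 (without saline 1, saline 2, LPS 1, LPS 2, saline 3, saline 4, LPS 3, LPS 4, -0.23 to -0.18). Pfkl was -0.15 (not past the test) and Pfkm -0.19 (not past the test) with the median signal of each array as a covariate. Pfkl was -0.16 (not past the test) and Pfkm -0.086 (not past the test) when scaled to each array's median. Pfkl was 0.002 (not past the test) as the mean of a gene's probes.

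Among genes of oxidant and iron handling 19 of 29 measured genes rose and 5 fell (19 and 5 adjusted over the list alone), with a median of 0.49 (camera adjusted p = 0.00143, and adjusted p = 0.518 with an estimated correlation). Beside Acod1 and Lcn2, the iron oxidase ceruloplasmin, Cp, rose by 2.76 ± 0.19, or by 1.44 as the mean of its probes. Slc40a1, the gene of the iron exporter ferroportin, fell by 1.85 ± 0.22, and Slc7a11, a cystine transporter gene, fell by 0.62 ± 0.17. In the list of prostaglandin and leukotriene enzymes and receptors 11 of 17 measured genes rose and 3 fell (12 and 3 adjusted over the list alone), with a median of 0.74 (camera adjusted p = 0.0285, and adjusted p = 0.518 with an estimated correlation). The prostaglandin receptor gene Ptger4 (2.55 ± 0.19) and Pla2g7 (1.16 ± 0.17) rose, and the synthase genes Ltc4s (-1.39 ± 0.18) and Ptgds (-1.38 ± 0.27) fell. The camera adjusted p of this list was 0.0833 with quantile normalization. Without LPS replicate 3 the counts were 19 higher and 4 lower for oxidant and iron handling and 12 higher and 3 lower for the prostaglandin list. Slc7a11 was -0.31 (not past the test) and Ptgds -0.94 (not past the test) with the median signal of each array as a covariate. Slc7a11 was -0.40 (not past the test) when scaled to each array's median. Slc7a11 was -0.31 (not past the test) as the mean of a gene's probes.

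Lists of blood cell markers differed in how many members rose. Among monocyte markers 13 of 18 measured genes rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 1.45 (camera adjusted p = 3.77e-05, and adjusted p = 0.518 with an estimated correlation). Haptoglobin, Hp, rose by 2.15 ± 0.24 and Ly6c2, a surface antigen of inflammatory monocytes, by 2.11 ± 0.20. Among neutrophil markers 11 of 25 measured genes rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 0.0166, and adjusted p = 0.659 with an estimated correlation). Beside Lcn2, Wfdc21 rose by 2.84 ± 0.33, and Csf3r, the receptor of the granulocyte growth factor, fell by 0.23 ± 0.07. The camera adjusted p of this list was 0.122 without LPS replicate 3, with a median of 0.52 and counts of 11 higher and 2 lower. Its mean change was -0.39 to 0.63 on the saline arrays and 0.35 to 1.12 on the LPS arrays, so the groups overlapped. Within each slide column the LPS array was the higher. Among T and NK cell markers 5 of 15 measured genes rose and 4 fell (8 and 4 adjusted over the list alone) (camera adjusted p = 0.364). The granzyme genes Gzmb (4.37 ± 0.52, well above background on 1 of 4 saline arrays, 3.26 with signals floored at the lowest well above background) and Gzma (2.27 ± 0.15) rose, and Cd28 and Il7r (-1.11 ± 0.22) fell. Among B cell markers 4 of 10 measured genes rose and 1 fell (4 and 1 adjusted over the list alone) (camera adjusted p = 0.35), with Ms4a1 (1.09 ± 0.17, or 0.37 and not past the test as the mean of its probes) and Fcmr (0.99 ± 0.24) risen and Cd22 (-0.42 ± 0.10) fallen. Among dendritic cell markers 4 of 11 measured genes rose and 5 fell (4 and 5 adjusted over the list alone) (camera adjusted p = 0.518), with the lymph node homing receptor gene Ccr7 (2.39 ± 0.19) and Bst2 (1.62 ± 0.15) risen, and Cd209a (-4.91 ± 1.04) and Clec9a (-2.92 ± 0.51) fallen. Cd209a was well above background on 2 of 4 LPS arrays and Clec9a on 1 of 4, so part of each change is against background. With signals floored at the lowest well above background Clec9a was -1.47, and with normexp background and the 75th percentile it was -0.19 and Cd209a -1.82. Cd209a was -6.06 without LPS replicate 3, -4.22 without LPS replicate 2, -3.84 as the mean of its probes and -3.26 and not past the test with the median signal as a covariate. Of mast cell and basophil markers 1 of 8 measured genes rose and 0 fell (0 and 0 adjusted over the list alone) (camera adjusted p = 0.703), and the protease gene that rose was Mcpt4 (0.74 ± 0.26). Leave-one-out fits ended the calls of Csf3r (without saline 2, LPS 1, saline 3, saline 4, LPS 4, -0.23 to -0.20) and Mcpt4 (without saline 1, saline 2, LPS 2, saline 4, LPS 3, LPS 4, 0.55 to 0.81). Gzmb was 0.90 and Il7r -0.52 with normexp background and the 75th percentile. Csf3r was -0.17 (not past the test), Il7r -0.81 (not past the test), Fcmr 1.03 (not past the test) and Clec9a -1.89 with the median signal of each array as a covariate. Csf3r was -0.012 (not past the test) and Cd22 -0.21 (not past the test) when scaled to each array's median. Cd22 was -0.33 (not past the test) as the mean of a gene's probes. Mcpt4 was 0.69 (not past the test) with quantile normalization. Mcpt4 was 0.58 (not past the test) when scaled over probes well above background on all arrays.

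Of the lists for other cells, 4 were lower in LPS. Among astrocyte markers 0 of 14 measured genes rose and 13 fell (0 and 14 adjusted over the list alone), with a median of -0.99 (camera adjusted p = 2.65e-06, and adjusted p = 0.518 with an estimated correlation), and the bicarbonate transporter gene Slc4a4 (-1.25 ± 0.13) and the glutamate transporter gene Slc1a3 (-1.17 ± 0.14) fell. In the oligodendrocyte lineage 0 of 14 measured genes rose and 9 fell (1 and 10 adjusted over the list alone), with a median of -0.73 (camera adjusted p = 0.00426, and adjusted p = 0.518 with an estimated correlation), and Enpp6 (-1.10 ± 0.37, well above background on 2 of 4 LPS arrays) and the transcription factor gene Olig1 (-0.99 ± 0.17) fell. Among vascular cell markers 0 of 15 measured genes rose and 10 fell (0 and 13 adjusted over the list alone), with a median of -0.67 (camera adjusted p = 2.81e-04, and adjusted p = 0.518 with an estimated correlation), and the pericyte gene Rgs5 (-1.54 ± 0.33) and Vtn (-1.18 ± 0.13) fell. Among erythroid markers 0 of 7 measured genes rose and 5 fell (0 and 5 adjusted over the list alone), with a median of -1.37 (camera adjusted p = 0.00855, and adjusted p = 0.518 with an estimated correlation), and the globin genes Hbb-bt (-1.51 ± 0.28) and Hbb-b1 (-1.50 ± 0.37) fell. Among neuron markers 1 of 13 measured genes rose and 2 fell (1 and 1 adjusted over the list alone) (median -0.68, camera adjusted p = 0.0749), with Gad1 (0.74 ± 0.17) risen, and Rbfox3 (-1.06 ± 0.14) and Map2 (-0.84 ± 0.29) fallen. Among choroid plexus and ependyma markers 0 of 10 measured genes rose and 2 fell (0 and 0 adjusted over the list alone) (median -0.97, camera adjusted p = 0.0603), with Tmem212 (-1.43 ± 0.50) and Ccdc153 (-1.23 ± 0.40) fallen. With the median signal of each array as a covariate the median was -0.077 for neuron markers and turned to 0.45 for choroid plexus and ependyma markers. In that fit it was -0.67 for astrocyte, -0.49 for oligodendrocyte lineage, -0.25 for vascular and -1.11 for erythroid markers. Enpp6 was -0.074 (not past the test) and Hbb-b1 -0.49 with normexp background and the 75th percentile. Enpp6 was -0.64 (not past the test), Rgs5 -0.77, Hbb-b1 -1.11 (not past the test), Map2 -0.16 (not past the test) and Tmem212 -0.40 (not past the test) with the median signal of each array as a covariate. Ccdc153 was -0.35 (not past the test) with the median signal of each array as a covariate. Map2 was -0.65 (not past the test) as the mean of a gene's probes. Enpp6 was -0.85 (not past the test) and Map2 -0.80 (not past the test) with quantile normalization.

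The mean change of astrocyte markers was -0.68 on LPS replicate 3 and -1.17 to -0.70 on the other LPS arrays, that of vascular markers was -0.40 on LPS replicate 3 and -1.06 to -0.59 on the other LPS arrays and that of neuron markers was 0.29 on LPS replicate 3 and -0.85 to -0.72 on the other LPS arrays. Choroid plexus and ependyma markers stood at 0.30 on LPS replicate 3 and -2.23 to -0.53 on the other LPS arrays. The saline arrays ran from -0.32 to 0.30 for neuron markers and from -0.91 to 0.61 for choroid plexus and ependyma markers. Over all arrays the groups thus overlapped in both. Within each slide column the LPS array was the lower in both lists. For neuron markers the column of LPS replicate 3 hardly differed (0.293 against 0.3 on saline replicate 3). Without LPS replicate 3 the counts were 0 higher and 13 lower for astrocytes, 2 higher and 9 lower for the oligodendrocyte lineage, 0 higher and 13 lower for vascular cells, 0 higher and 6 lower for erythroid cells, 1 higher and 8 lower for neurons and 0 higher and 5 lower for choroid plexus and ependyma. The neuron list was then past the test (camera adjusted p = 0.0101, median -1.02), as it was without saline replicate 2 (-0.81), with adjusted p = 0.51 and adjusted p = 0.646 with an estimated correlation. The choroid plexus list was past it with slide column as a block (camera adjusted p = 0.0162), where each column held 1 saline and 1 LPS array, and without LPS replicate 3 (-1.42), LPS replicate 4 (-1.07) or saline replicate 2 (-1.31), and in these fits the lowest adjusted p = 0.638 with an estimated correlation. With the median signal of each array as a covariate, the erythroid call ended with a median of -1.11. Leave-one-out fits ended the calls of Enpp6 (without saline 2, LPS 1, LPS 2, saline 3, saline 4, LPS 3, -1.10 to -0.90), Map2 (without saline 1, saline 2, LPS 1, LPS 2, saline 3, saline 4, LPS 4, -0.93 to -0.69), Tmem212 (without saline 1, LPS 1, LPS 2, saline 3, saline 4, -1.48 to -1.02) and Ccdc153 (without LPS 1, LPS 2, saline 3, saline 4, -1.12 to -0.92). The Y-linked genes Eif2s3y (0.07 ± 0.15, adjusted p = 0.726) and Kdm5d (-0.07 ± 0.07, adjusted p = 0.443) were well above background on all 8 arrays of these male mice. Each tube pooled 2 mice, so this alone does not show that both were male. Xist and Tsix did not pass the background filter and were not tested. With quantile normalization Eif2s3y was -0.04 and Kdm5d -0.02, and scaled to each array's median they were 0.28 and 0.15.

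**Figure D2:**
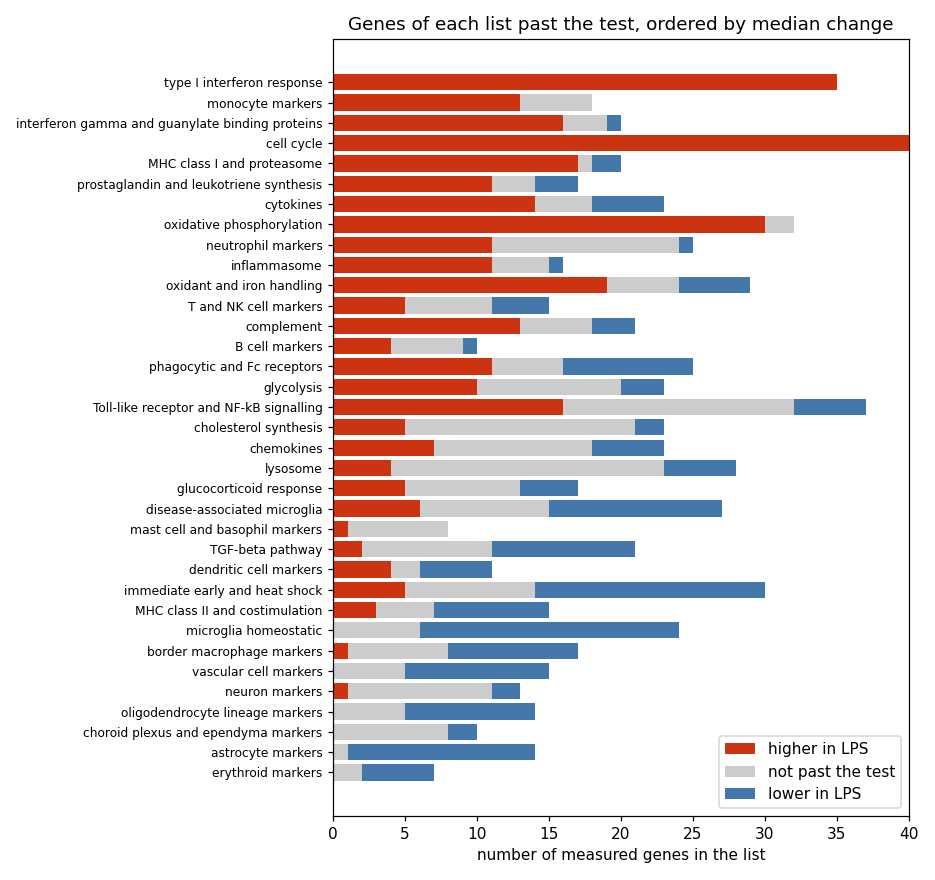
Number of measured genes in each of the 35 lists that were higher (red), lower (blue) or not past the test (grey) in LPS, on a linear axis, with lists ordered by median change. All 35 type I interferon genes and all 40 cell cycle genes were higher.

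The arrays parted by treatment, with 1 exception in position. The first principal component held 68.0% of the variance, and the saline arrays lay at -72.8 to -21.8 while LPS replicates 1, 2 and 4 lay at 56.8 to 85.4. LPS replicate 3 lay at -9.8, and its mean correlation was 0.984 with the saline arrays and 0.982 with the other LPS arrays. All arrays came from 1 slide and 1 scan. With slide row as a block 9991 genes changed, and with slide column 13620. Of the 177 named genes past the test, slide row as a block ended the calls of 10 and slide column of 0. Within the first row, 2 arrays against 2, 5601 genes changed, and within the second, which held LPS replicate 3, 5 did, with 5152 at an unadjusted p under 0.05. Camera called 22 of 35 lists, 23 with slide column as a block (choroid plexus and ependyma markers beside the 22), 24 in the first row, 22 in the second, and 0 with an estimated correlation, where the lowest adjusted p was 0.518. fry called 27.

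**Figure D3:**
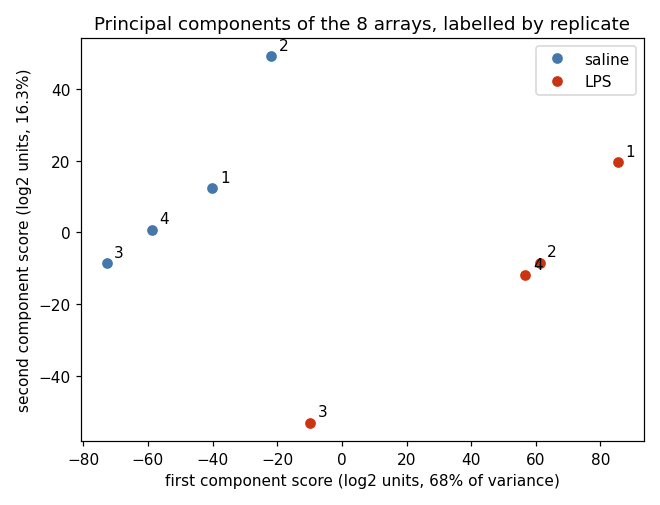
Scores of the 8 arrays on the first and second principal components of normalised log2 signal, in log2 units, labelled by replicate, with saline in blue and LPS in red. LPS replicate 3 lies at -9.8 on the first component, between the saline arrays and the other LPS arrays.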

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

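All tests below other than the splits of the arrays were chosen, and their limits set, after results that bear on them were seen, and the covariate and the removal of the abundance trend were alternatives chosen after seeing the data. One sample lay far from the other 3 of its group in 29 of 442 comparisons, where chance gives about 1 in 20. On the normalised log2 scale LPS replicate 3 stood apart in Cd72 at 3.75 (others 4.68 to 4.81), Cgn at -0.22 (others -3.64 to -3.10), Cd28 at -0.82 (others -2.70 to -2.65), Tslp at -2.38 (others -4.50 to -4.23), Clec10a at 3.45 (others 2.80 to 2.91), Bst2 at 5.48 (others 5.97 to 6.00), Socs3 at 6.72 (others 7.20 to 7.24), Psmb9 at 3.60 (others 4.21 to 4.24), Psmb8 at 4.47 (others 4.99 to 5.04), Ank at 0.93 (others -0.26 to -0.14), Ctsc at 5.86 (others 6.31 to 6.41), Ctsh at 6.61 (others 6.88 to 6.93), Ctsz at 7.46 (others 7.72 to 7.76), Cox7b at 5.40 (others 5.84 to 5.93), Slc40a1 at 2.85 (others 1.85 to 1.93) and Eif2s3y at 1.28 (others 1.53 to 1.57). LPS replicate 4 stood apart in Lcn2 at 6.28 (others 5.81 to 5.83), Mefv at 0.93 (others 0.00 to 0.15), Lilrb4a at 5.79 (others 5.22 to 5.32) and Hexa at 5.83 (others 6.00 to 6.02). Saline replicate 2 stood apart in Cd209b at 0.04 (others -0.22 to -0.20), Ppbp at -1.11 (others -1.79 to -1.73) and Ptgds at 6.59 (others 7.26 to 7.29), and saline replicate 3 in Cxcl13 at -5.97 (others -7.38 to -7.27) and Hspa1b at 2.99 (others 1.77 to 1.95). As mean changes of a list, LPS replicate 3 stood apart in neuron markers at 0.29 (others -0.85 to -0.73), Toll-like receptor and NF-kB signalling at 0.25 (others 0.47 to 0.51) and inflammasome at 0.37 (others 0.65 to 0.67), and saline replicate 4 in dendritic cell markers at 0.12 (others -0.05 to -0.02).

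LPS replicate 3 lay nearer the saline arrays than the other LPS arrays did. A swap with a saline array is argued against, since 0 saline arrays reached the lowest LPS score of the interferon list. Its position was not removed with the abundance trend, after which its mean correlation with the LPS arrays minus that with the saline arrays was -0.0034. Its median processed signal was 17.28, against 11.71 to 13.77 on the other LPS arrays and 15.51 to 21.54 on the saline arrays. Saline replicate 3, in the same slide column, had the highest signal (21.54) and the lowest first component score (-72.8). Effects of signal level or slide column beyond that trend were not tested here and stay open. RNA of saline brains mixed into this sample may contribute and stays open: over the 182 genes at least 4-fold higher without it, its median lay at -0.52 against the other LPS arrays, between the limits set for and against, and its median share of their log2 change was 80.3% in these genes, 64.6% in genes at least 2-fold higher and 39.2% in genes at least 2-fold lower. A weaker response in the mice of that tube, the biological explanation, would also give smaller changes and stays open. The genes were chosen in a fit without LPS replicate 3, and no such share was computed for the other LPS replicates.

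Of 6 lists of markers of other cells, 5 of them of brain cells, camera called 4 lower in LPS and 0 with an estimated correlation, with a median of -0.79 over the 73 members of all 6. An equal loss of all these cells, erythroid cells included, cannot be decided by the spread of the list medians. They lay 0.70 apart, more than shuffled members gave (permutation test with 10000 shuffles, p = 0.0033). The shuffles treat members as independent, though markers of a cell type can move together, and an equal loss need not give equal log2 changes. For the 5 lists of brain cells the medians lay 0.33 apart (permutation test with 10000 shuffles, p = 0.2545), so fewer brain cells of other types carried through the sort could account for their fall and stay open, as do unequal losses. The abundance trend of the arrays is argued against as the whole cause, since the median was -0.751 with the trend removed. The signal level of the arrays cannot be told apart from the treatment, since median signal differed between the groups. With the median signal as a covariate the median was -0.345 over all members. By list it was -0.671 for astrocytes, -0.488 for the oligodendrocyte lineage, -0.252 for vascular cells, -1.109 for erythroid cells, -0.077 for neurons and 0.45 for choroid plexus and ependyma. An effect of LPS on these cells is a hypothesis that the design leaves open.

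Of 18 monocyte markers 13 rose and 0 fell, and of 25 neutrophil markers 11 rose and 1 fell. The camera calls of both lists ended with an estimated correlation (adjusted p = 0.518 for monocytes and 0.659 for neutrophils). That of the neutrophil list also ended without LPS replicate 3 (camera adjusted p = 0.122). Its mean changes overlapped between the groups, though within each slide column the LPS array was the higher. The signal level of the arrays is argued against as the whole cause, since 91.3% of the risen markers of both lists were still called with median signal as a covariate. That share covers only markers already called, and median signal differed between the groups, so a part played by it is not excluded. For the monocyte markers no cause other than the signal level was tested, cells from blood included. Blood neutrophils among the sorted cells could account for part of the rise of neutrophil markers and stay open. Of these markers 44.0% rose, which by the limit first set, under 50%, argued against blood neutrophils. Only after that was seen were 6 granule genes of marrow precursors set apart, and 57.9% of the other 19 rose, between the limits. The CD11b sort would keep such cells, S100a8 rose by 1.59 ± 0.29 and S100a9 by 1.38 ± 0.29, while Retnlg, also abundant in blood neutrophils, was -0.07 ± 0.35 (adjusted p = 0.875), and expression of such genes by microglia was not tested.

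Chance is argued against for the count of changed genes, as 1 of 35 splits of the arrays into 4 and 4, the real one, gave as many (11104, against 600 in the highest other). The same held for changes of at least 2-fold (2099 against 489, in 1 of 35 splits). This is the lowest share that 35 splits can give, so chance is not excluded. The other splits mix the treatments, which widens the spread within their groups and lowers their counts. For the count of lists called by camera 2 of 35 splits gave 22 or more, with 22 in the highest other. This cannot decide on chance, which stays open, since that other split kept most of the treatment contrast. Splits with 2 saline and 2 LPS arrays on each side gave 0 changed genes and still 3 to 13 lists. Camera at the preset correlation thus called lists where treatment was balanced. The other split with 22 lists put LPS replicate 3 in the place of saline replicate 3.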

How the results depend on the processing

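The median signal covariate and the removal of the abundance trend were chosen after seeing the data. Of 177 named genes past the test, 127 kept their direction and side of the threshold in all of the 25 alternatives that gave them a value (18 had none with probes well above background on all arrays), and 160 in the 8 fits that left out 1 array. Of 22 gene lists past the test, 16 did so in these 25 and 20 in the 8 fits, but 0 did with an estimated correlation. Of 13 lists not past the test 6 were past it in some alternative, and of 5 named genes not past it 4 were. The authors' values gave 11105 changed genes. Signal over background leaves only bounds for genes not well above it on any array of a group, which include 39 genes called higher and 93 called lower. Among the lowest 10% of genes by signal 233 were at least 2-fold lower and 62 higher, and among the highest 10% these were 20 and 109. Leaving out 1 array gave 8730 to 13262 changed genes, 1655 to 3415 changed at least 2-fold, 694 to 1104 higher and 961 to 2311 lower by that much, and 21 to 24 lists, with the highest 2-fold counts without LPS replicate 3. It gave medians of -0.029 to 0.106 for chemokines, and -0.025 to 0.063 for Cx3cr1 and -0.046 to 0.186 for Eif2s3y. Normexp background with the 75th percentile gave 647 genes at least 2-fold changed (422 higher, 225 lower), and with quantile normalization 606 (268 and 338). Both used the offset of 50, so the drop is not that of background correction alone. Scaling to each array's median gave 2619 genes lower, and 1536 higher and 732 lower by at least 2-fold. Scaling over probes well above background on all arrays gave 514 genes at least 2-fold higher. Array weights gave 3322 genes at least 2-fold changed, with 2304 lower. They enlarged the fold of 5 of the 177 named genes by over 1.5 times, among them Cgn (-4.02), Asb11 (-3.98), Cd209a (-6.27) and Clec9a (-3.53). The covariate gave 4132 genes higher and 1032 at least 2-fold changed (506 higher, 526 lower), and kept 6742 of the 11104 calls. Single probes gave 16856 changed probes, 7741 of them lower, because more features were tested. The test fry called 27 lists. These values changed sign: with quantile normalization chemokines -0.17, glycolysis -0.001, phagocytic and Fc receptors -0.061, Eif2s3y -0.037, Ccl2 -0.15 and Cx3cr1 -0.15, with each array's median disease-associated microglia 0.053, lysosome 0.15, glucocorticoid response 0.052, Hmgcs1 0.012 and Kdm5d 0.15, and with scaling over probes well above background on all arrays chemokines -0.15, cholesterol synthesis -0.022, Eif2s3y -0.087, Ccl2 -0.014 and Cx3cr1 -0.13. With normexp and the 75th percentile they were mast cell and basophil markers 0.001 and chemokines -0.012, and with normexp and quantiles chemokines -0.17, phagocytic and Fc receptors -0.041, Eif2s3y -0.027, Ccl2 -0.17 and Cx3cr1 -0.18. Others were phagocytic and Fc receptors -0.012 and Pfkl 0.002 with the mean of a gene's probes, B cell markers -0.053 and glucocorticoid response 0.024 with single probes, and dendritic cell markers 0.10 and chemokines -0.023 with probes well above background on all arrays. With the covariate they were mast cell and basophil markers 0.051, choroid plexus and ependyma markers 0.45, chemokines -0.075, Toll-like receptor and NF-kB signalling -0.020, Eif2s3y -0.069, Ccl2 -0.075 and Cx3cr1 -0.13, and with the trend removed chemokines -0.19, glycolysis -0.004, phagocytic and Fc receptors -0.014, Eif2s3y -0.036, Kdm5d 0.036, Ccl2 -0.19 and Cx3cr1 -0.30. Unless stated, the cause was not tested.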

Other observations

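Low-signal genes tended to be lower in LPS and high-signal genes higher. Among the lowest 10% of genes by mean signal the median change was -0.27, and among the highest 10% it was 0.34. Genes named outside the rule were chosen after their values were seen: S100a9 and Retnlg above, and the granule genes of marrow precursors such as Camp (-0.89 ± 0.44, adjusted p = 0.126) and Ngp (-0.03 ± 0.38, adjusted p = 0.948), which were not past the test.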
